A study of Zea mays with 144 samples.

How the data were processed

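Gene expression was measured by RNA sequencing in grain of 8 maize inbred lines at 6 stages of development, with 3 biological replicates per line and stage, per the labels. That design gave 48 groups and 144 libraries. The plants were grown in a randomized field trial and pollinated by hand with their own pollen, and RNA was extracted with TRIzol and made into libraries with a NEBNext Ultra kit, per the labels' protocols. The labels do not say how the biological replicates relate to the field replications or to single plants or ears, so a p-value here measures the spread between libraries of 1 group, part of which may be technical. Whether the libraries kept the strand of the RNA was not given in the sources used here, so genes that overlap on opposite strands cannot be told apart with certainty.

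Trimmomatic 0.38, HISAT2 2.0.5, StringTie 1.3.5 and edgeR without a version are named in the submitters' processing notes, with the genome build B73 RefGen_v4. The authors deposited 1 StringTie gene abundance table per library, and per the file headers each table gives, for every gene, its mean read coverage (a signal that is not scaled to library size), its FPKM and its TPM, with the gene's chromosome, strand, start and end. FPKM stands for fragments per kilobase of gene and 1000000 fragments, and each deposited TPM column, the same measure rescaled, summed to 1000000. Each table held 46430 gene identifiers, with 0 duplicates, and TPM was a constant multiple of FPKM within each of the 144 libraries. Reads from near-identical genes such as the zein copies can be shared out by the assembler, so values of single zein genes are uncertain. No table of raw counts was used here, so no count model was fitted. Read depth was recovered from the deposited coverage and FPKM columns. Their ratio is the amount of aligned sequence in Gb for every gene whose coverage and FPKM rest on the same length, and the most common ratio in each library was shared by 47.1% to 51.7% of genes with FPKM of at least 0.5, within a tolerance of 0.1%. This estimate assumes StringTie's definition of both columns. A gene at 1 TPM in a library of that size rests on few fragments, which is why low genes were filtered and a pseudocount was used.

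Gene names were taken only from the name column of the deposited tables, which named 6542 identifiers. A RefSeq table of another assembly, Zm-B73-REFERENCE-NAM-5.0, matched 518 identifiers and 0 of the maize gene models, and it was not used for names or positions. Genes were tested if they had a TPM of at least 1 in at least 3 libraries, which left 28780 genes, of which 3804 (13.2%) had a proper name. Locus, probe and small RNA family codes were not counted as names. Coordinates are gene spans in B73 RefGen_v4 as the deposited tables give them, and exons and untranslated regions were not analysed here.

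The values tested were log2(TPM + 1), so a log2 fold change understates the change of low genes. Folds averaged over lines are means of log values and can exceed the ratio of mean TPM where lines differ. Linear models with 1 mean per line and stage were fitted to all 144 libraries with limma 3.58.1 in R 4.3.3, with moderated variances and a mean-variance trend, and p-values were adjusted by Benjamini and Hochberg. A gene was called at an adjusted p below 0.05 and an absolute log2 difference of at least 1. Contrasts were 56 against 21 days after pollination (DAP) and each stage against the one before it, averaged over the 8 lines with equal weight, 56 against 21 DAP within each line, and each line against the mean of the other lines over all stages. Moderated F tests covered the stage effect, the line effect and the line by stage interaction, with the same adjusted p and a range of means (for the interaction, of the 56 against 21 DAP fold) of at least 1 on the log2 scale. The 25 gene lists and a list of organelle-encoded genes were set from general knowledge of maize grain. The lists were tested on the 56 against 21 DAP contrast with limma's camera at a preset correlation, and again with an estimated correlation. Their summed share of TPM was compared over the 8 lines by an exact two-sided sign-flip permutation test, whose smallest possible p is 0.0078. Other computations and the figures used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.

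The lists, tests, thresholds, alternatives and the rule for named genes were set before the data were examined. The rule took, for 56 against 21 DAP, the 10 largest rises and the 10 largest falls among called and named genes with the same sign in all 8 lines and a mean TPM of at least 5. For each stage against the one before it, it took the 3 largest rises and falls under the same conditions, where there were as many. From each gene list it took the called member with the largest fold in each direction and the most abundant member. It took the 10 genes with the largest range of line means, the 10 with the largest interaction F, the largest difference in each direction for each line, and 12 genes of known function whatever they showed. Since most called genes had no name, 2 rising and 2 falling identifiers without a name are also given. All other genes named in the text are said to have been chosen after their values were seen.

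The fitting code was tested on simulated data with known changes in 66 or 67 genes at each of 3 sizes among 28780 genes. The changed genes were drawn from those with a mean log2(TPM + 1) of at least 3. Values were drawn independently for each gene, with no other difference between lines or stages. The recovery of lower genes, and false calls among correlated genes, were therefore not tested. For 56 against 21 DAP averaged over lines, 100% of genes changed by 1.5, 2 and 3 on the log2 scale were recovered with 0 false calls. Within 1 line, the recovery was 77.3%, 95.5% and 91.0% with 6 false calls, and for 1 line against the others it was 100% at each size with 0 false calls. For the stage effect it was 100%, 100% and 98.5% with 0 false calls, for the line effect 100%, 100% and 98.5% with 3 false calls, and for the interaction 40.9%, 74.6% and 88.1% with 3 false calls.

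The counts of called genes and the named genes were recomputed with pseudocounts of 0.1 and 5, with no filter and with a filter on mean TPM, with median-of-ratios scaling, with quantile normalization, with TPM recomputed without the zein list (zein genes excepted), with FPKM, with robust variances, with the replicate number of the labels as a block, and without each replicate number. Leaving out each line, and the line as the unit, covered the contrasts averaged over lines and the stage effect. The counts within lines were also taken from the 6 libraries of a contrast alone. The camera lists were recomputed with both scalings and the estimated correlation, and the summed shares without each replicate number, without the zein list and without organelle-encoded genes. One alternative was chosen after seeing the data. For each line, 252 to 269 genes that were on in some lines and off in others served as a profile (on at a TPM of at least 5, off below 0.5). A library's match is the percentage of those genes whose state at a TPM of 2 was that of the line, and the alternative leaves out the libraries that matched the line in their label at less than 85%. No pair of libraries held identical values.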

Results

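RNA sequencing was used to follow the transcriptome of maize (Zea mays) grain in 8 inbred lines, called Q1 to Q8 in the labels, every 7 days from 21 to 56 days after pollination (DAP). The design allowed 3 questions: how the grain transcriptome changed with age, how the lines differed, and whether the change with age differed between lines. The grain consists of the endosperm, which stores starch and the prolamin proteins called zeins, the embryo with its oil and globulins, and the maternal pericarp. Each of the 48 groups of line and stage had 3 biological replicates. The estimated depth was 5.997 to 9.75 Gb of aligned bases per library, with a median of 7.34 Gb. The stage means ranged from 6.87 ± 0.369 at 35 DAP to 8.04 ± 0.919 at 49 DAP (SD, n = 24 libraries). The number of genes with a TPM of at least 1 was 20703 ± 1025 at 21 DAP and 20500 ± 843 at 56 DAP (SD, n = 24). Log values of replicates of 1 group correlated across genes at r = 0.873 to 0.991, with a median of 0.974 over all replicate pairs. The first principal component held 31.9% of the variance and the second 11.2%.

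The 10 most abundant genes of each library took 37.6% ± 4.44 of the TPM sum at 21 DAP and 21.8% ± 6.29 at 56 DAP (SD, n = 24), so a fall of a few transcripts moved the share left for all others. In addition, 13 libraries did not match the on/off genes of the line in their label, 8 of them at 28 DAP, 4 at 35 DAP and 1 at 42 DAP. They carry the labels Q1, Q2, Q4, Q5 and Q6, and none was labelled 21, 49 or 56 DAP. The other 131 libraries matched their line at 89.4% to 100%. All libraries were kept as labelled. Of the counts and named genes recomputed without those 13 libraries, values are given where they moved by more than 1.5 times or a call changed.

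**Figure D1:**
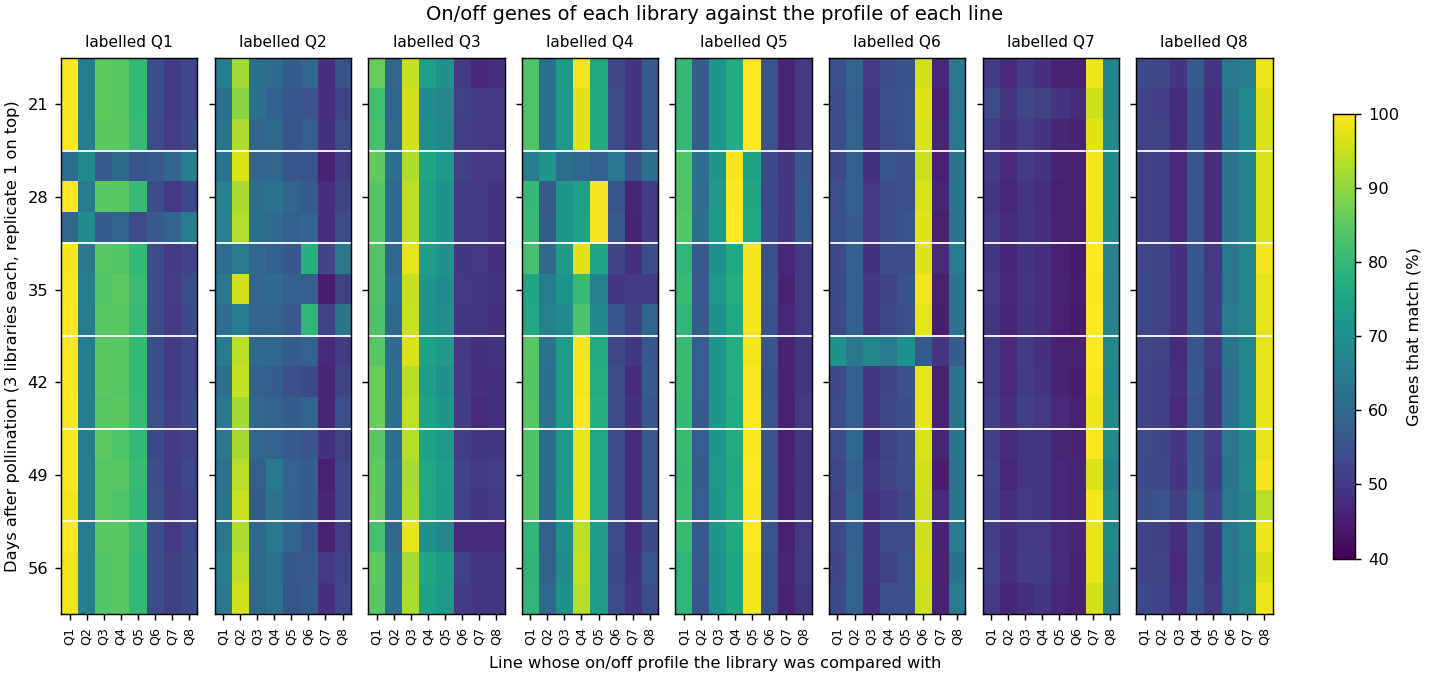
Match of each library to the on/off gene profile of each of the 8 lines, in percent of the genes compared (colour). Each panel holds the 18 libraries that carry 1 line label, in the order of the stages from 21 to 56 DAP (vertical axis, 3 libraries per stage). The horizontal axis gives the line whose profile was used. In all, 131 libraries matched their own line at 89.4% or more, and the libraries labelled Q5 at 28 DAP matched Q4 at 99.2% to 100%.

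The first comparison asked which transcripts changed between 21 and 56 DAP, averaged over the 8 lines. Transcripts of zeins, the main storage proteins of the endosperm, made up 32.6% ± 2.85 of the TPM sum at 21 DAP and 8.34% ± 10.9 at 56 DAP (SD over lines, n = 8 lines). The share was lower at 56 DAP in 7 of 8 lines (exact sign-flip permutation test, two-sided, p = 0.0156, adjusted over the 25 lists p = 0.017). The share of starch synthesis genes went from 0.863% ± 0.189 to 0.368% ± 0.290 and was lower in 8 of 8 lines (exact p = 0.00781, the smallest the test can give, adjusted p = 0.0115). In the opposite direction, the share of LEA proteins and dehydrins, which protect drying seed tissue, went from 0.193% ± 0.0477 to 3.08% ± 1.69. That of the globulins, storage proteins found mainly in the embryo, went from 0.972% ± 0.274 to 2.86% ± 1.23, and both were higher in 8 of 8 lines (exact p = 0.00781, adjusted p = 0.0115). The oil body list went from 0.819% ± 0.222 to 2.48% ± 0.573 and was also higher in 8 of 8 lines (exact p = 0.00781, adjusted p = 0.0115). Of the 25 lists, 24 passed this test, 16 higher and 8 lower at 56 DAP, so a pass is not particular to the lists named here. With the zein list left out of the sum, 5 of these passes were lost, and the cytosolic ribosomal proteins, which had not passed, reversed.

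**Figure D2:**
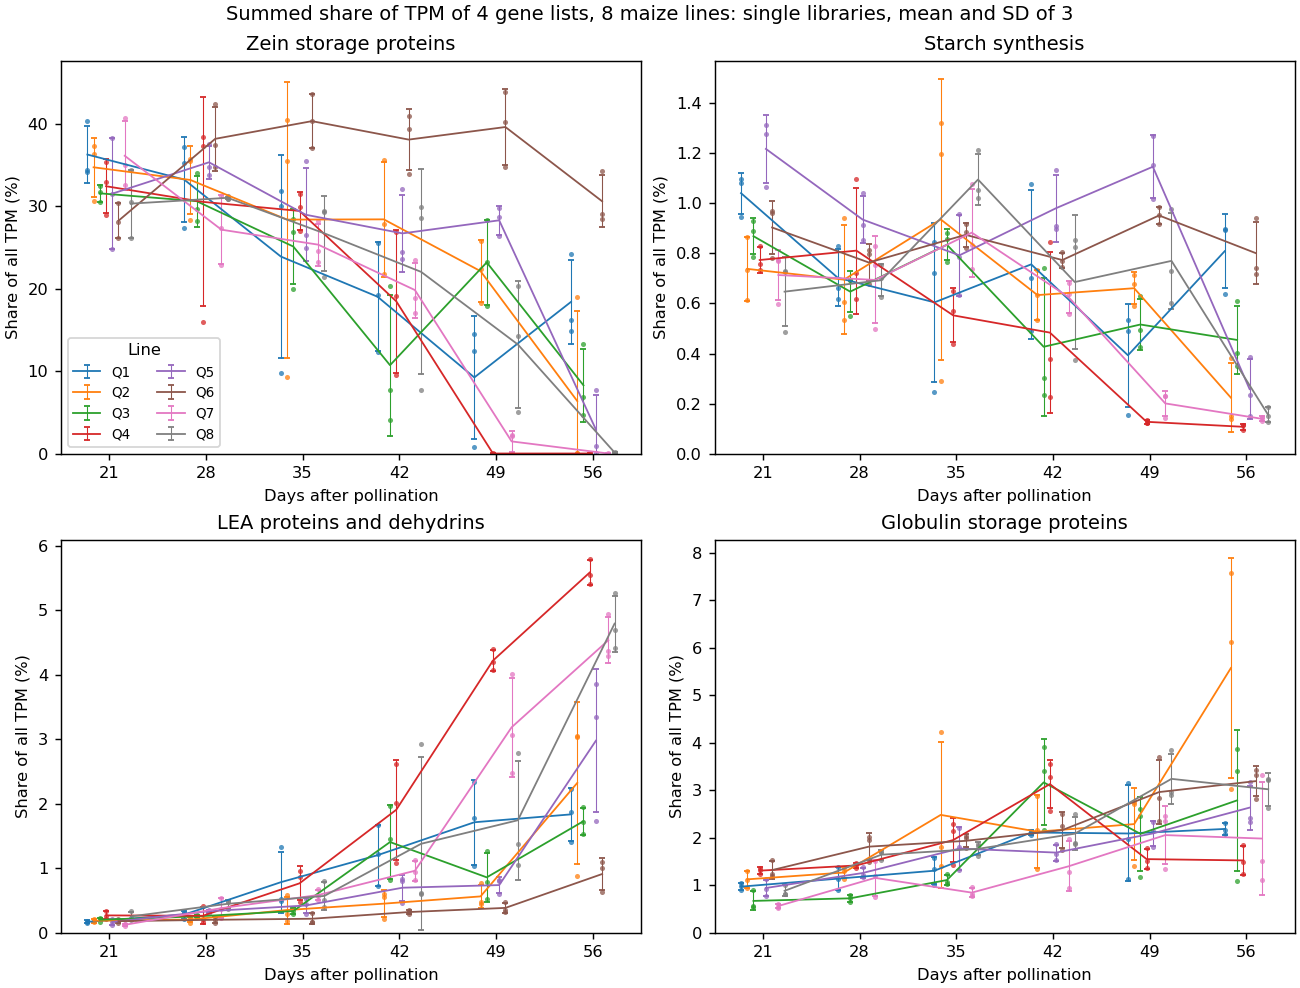
Summed share of the TPM of all genes (vertical axes, percent) against days after pollination (horizontal axes, points of the 8 lines shifted sideways for legibility) for zeins, starch synthesis genes, LEA proteins and dehydrins, and globulins. Dots are single libraries, lines join the means of 3 libraries and bars are SD; the mean zein share at 56 DAP was at most 0.142% in Q4, Q7 and Q8 and was 30.6% in Q6.

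All 13 zein genes tested fell between 21 and 56 DAP, with a median log2 change of -6.07. Among them, floury2 (Zm00001d049243, an alpha zein gene on chromosome 4, 22579361 to 22580152) went from 25160 ± 7738 to 3133 ± 3525 TPM (SD over lines, n = 8 lines; log2 change -6.88, SE 0.48, limma adjusted p = 5.17e-25). Floury4 (Zm00001d048851), another alpha zein gene, changed by -6.01. The gene named 22kD alpha zein5 (Zm00001d048806, chromosome 4, 5835517 to 5836317) had the largest change of the list at -7.40 (SE 0.47, adjusted p = 7.50e-28). The 27-kDa zein protein gene (Zm00001d020592), the most abundant gene of the whole series at a mean of 66240 TPM, went from 75560 ± 6890 to 30590 ± 41110 TPM. Camera placed the zein list below other genes with an adjusted p of 7.20e-10, and the call was lost with an estimated correlation (adjusted p = 0.193). Near-identical zein copies share reads, so the values of single copies are uncertain.

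Of 26 starch synthesis genes, 14 fell, 2 rose and 10 did not pass, with a median of -1.56. Those that fell included shrunken2 (Zm00001d044129; 964 ± 195.5 to 196.5 ± 248 TPM, log2 -4.88, SE 0.27) and brittle endosperm2 (log2 -4.41), which encode the large and small subunits of ADP-glucose pyrophosphorylase of the endosperm. Also lower were waxy1 (log2 -3.81), the granule-bound starch synthase that makes amylose, amylose extender1 (log2 -4.42), a starch branching enzyme, and sugary1 (log2 -2.51), a debranching enzyme. The largest rise of the list was in ADP glucose pyrophosphorylase2 (78.2 ± 21.2 to 308.5 ± 96.7 TPM, log2 1.91). The list's camera call (adjusted p = 0.000183) was lost with an estimated correlation (adjusted p = 0.251). Among 9 endosperm transcription factors, 2 fell and 7 did not pass. NAC-transcription factor 130 fell by 4.38 and opaque endosperm2, the activator of many zein genes, by 3.12 on the log2 scale. Prolamin-box binding factor1 had a log2 value of -0.88 and did not reach the fold threshold (camera adjusted p = 0.0393, and 0.251 with an estimated correlation).

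Lists for 2 endosperm regions that face maternal tissue and the embryo also held falls without rises. All 11 basal endosperm transfer layer genes fell, with a median of -3.79. Basal endosperm transfer layer9 went from 898.7 ± 445.2 to 61.2 ± 65.1 TPM (log2 -4.97; camera adjusted p = 3.80e-07, and adjusted p = 0.193 with an estimated correlation). Of 11 embryo surrounding region genes, 3 fell and 8 did not pass, and embryo surrounding region2 changed by -3.74 (camera adjusted p = 0.00136, and adjusted p = 0.193 with an estimated correlation). Genes of dividing cells were lower too: 14 of 22 cell cycle and DNA replication genes fell and 0 rose. The largest fall was in minichromosome maintenance7, a subunit of the replicative helicase (18.9 ± 6.77 to 4.41 ± 3.41 TPM, log2 -2.18; camera adjusted p = 2.20e-07, and adjusted p = 0.196 with an estimated correlation). Of 32 histone genes, 20 fell and 12 did not pass, with H4C7, a histone H4 gene, at -3.65 (camera adjusted p = 2.37e-09, and adjusted p = 0.251 with an estimated correlation). Of 29 lignin and secondary wall genes, 12 fell, 2 rose and 15 did not pass. Among those that fell were cellulose synthase7 at -2.31 and brown midrib3, a methyltransferase of lignin synthesis, at -2.22 (camera adjusted p = 0.000359, and adjusted p = 0.407 with an estimated correlation).

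The lists of desiccation and stress genes held more rises than falls. Of 10 LEA and dehydrin genes, 7 rose, 1 fell and 2 did not pass, with a median of 1.67 (camera adjusted p = 0.000167, and adjusted p = 0.193 with an estimated correlation). The gene dehydrin1 (Zm00001d037894, chromosome 6, 141324495 to 141325549), an abscisic acid responsive dehydrin, went from 129.7 ± 119 to 15570 ± 10730 TPM (SD over lines, n = 8 lines; log2 7.25, SE 0.23, adjusted p = 1.04e-50) and was called in each of the 8 lines. Responsive to abscisic acid30 (log2 6.09) and lea protein group3 (log2 5.46) rose as well, whereas dehydrin13 fell by 1.34. Of 11 heat shock proteins, 9 rose and 2 did not pass, with heat shock protein26 at 3.66 (camera adjusted p = 0.000359, and adjusted p = 0.259 with an estimated correlation). Of 45 antioxidant genes, 18 rose, 1 fell and 26 did not pass, and the largest rise was in glutathione transferase23 at 5.06 (camera adjusted p = 0.0152, and adjusted p = 0.56 with an estimated correlation). Among 27 defence and protease inhibitor genes, 15 rose, 5 fell and 7 did not pass (camera adjusted p = 0.0742). The extremes of this list were chitinase A1 (Zm00001d003190, chromosome 2, 35066062 to 35067313; 96.2 ± 77.8 to 7767 ± 4698 TPM, log2 7.12, SE 0.31) and corn-activated Hageman factor inhibitor1, a trypsin and amylase inhibitor of the grain (Zm00001d005230; 18810 ± 2290 to 2784 ± 4007 TPM, log2 -6.43, SE 0.35).

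Embryo storage and maturation genes were divided. Of 4 globulin and legumin genes, 2 rose and 2 fell, a list too short for camera. Its median of -1.36 had the opposite sign to the change of its summed share. Globulin1 (Zm00001d033447), the most abundant of them, went from 1652 ± 1061 to 21380 ± 11170 TPM (log2 3.90, SE 0.20) and was called in 8 of 8 lines, whereas legumin1 changed by -5.04. Of 6 oil genes, 3 rose, 1 fell and 2 did not pass (camera adjusted p = 0.346). Oleosin1, a protein of the oil body surface, changed by 1.65 and oleosin3 by 1.74, while WRI1 transcription factor2, a relative of an activator of fatty acid synthesis, changed by -2.03. Of 15 embryo and abscisic acid maturation regulators, 3 rose, 3 fell and 9 did not pass (camera adjusted p = 0.399). Viviparous1, a transcription factor of the abscisic acid response and dormancy, went from 11.9 ± 3.76 to 53.2 ± 32.7 TPM (log2 1.87), nine-cis-epoxycarotenoid dioxygenase4, an enzyme of abscisic acid synthesis, changed by 4.05, and WUSCHEL-related homeobox 2b by -2.40. The summed share of this list was 0.0101% at 21 DAP and 0.0188% at 56 DAP and higher in 7 of 8 lines (exact p = 0.0156, adjusted p = 0.017). It was not past the threshold once the zein list was left out of the sum (adjusted p = 0.0977).

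The camera test gave no call for the remaining lists. Their members that passed were 9 up and 5 down of 37 genes of abscisic acid signalling (adjusted p = 0.233), and 8 up and 6 down of 26 aquaporins (adjusted p = 0.923). There were 7 up and 3 down of 23 raffinose and trehalose genes (adjusted p = 0.923), and 5 up and 1 down of 19 photosynthesis genes (adjusted p = 0.463). They were 3 up and 1 down of 13 carotenoid genes (adjusted p = 0.122), 2 up and 2 down of 14 anthocyanin and flavonoid genes (adjusted p = 0.851), and 3 up and 0 down of 8 cell death and protein mobilisation genes (adjusted p = 0.0532). They were 2 up and 0 down of 31 cytosolic ribosomal proteins (adjusted p = 0.953), and 1 up and 1 down of 6 proteasome and ubiquitin genes (adjusted p = 0.908). Of the 3 amylases, too few for camera, beta amylase2 rose from 18.5 ± 7.77 to 712 ± 808 TPM (log2 4.36) and beta amylase5 fell by 2.01. Single members with large changes were galactinol synthase3, of the raffinose pathway (log2 5.27), TIP1-1, a water channel (log2 3.82), zeaxanthin epoxidase2 (log2 2.65), and yellow endosperm1, the phytoene synthase of yellow grain (log2 -1.83). The medians of the aquaporin, raffinose and trehalose, ribosomal protein and proteasome lists changed sign under at least 1 of the other scalings, so no direction is given for them. Organelle-encoded transcripts, the check for other RNA, took 0.0125% ± 0.0088 of the TPM sum at 21 DAP and 0.0376% ± 0.0154 at 56 DAP (SD, n = 24).

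**Figure D3:**
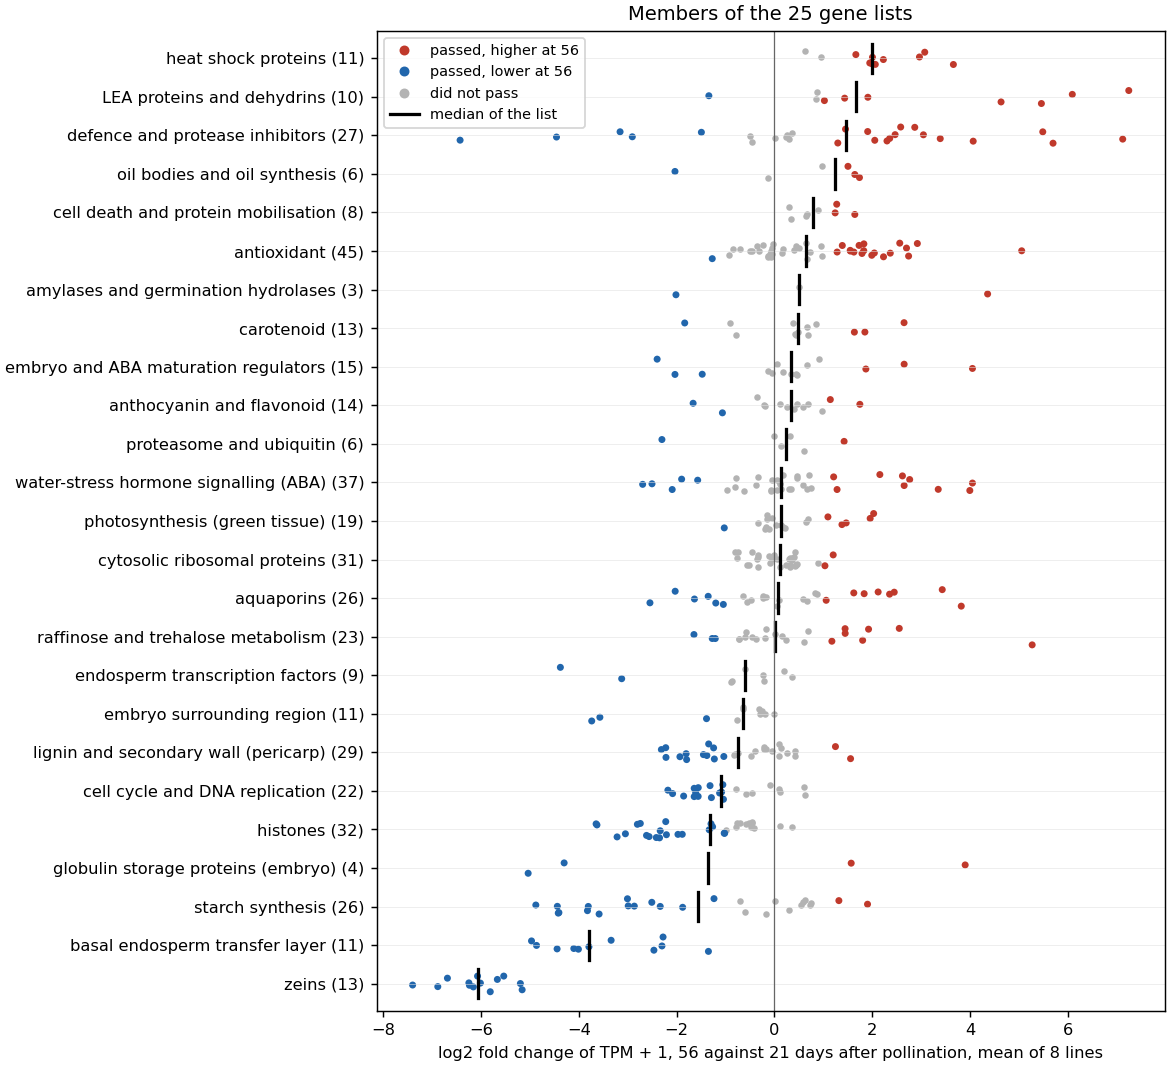
Log2 fold change of TPM + 1 between 21 and 56 DAP, averaged over the 8 lines (horizontal axis), for the tested members of the 25 gene lists (vertical axis, number of members in parentheses). Each dot is a gene, red and blue dots passed the test, grey dots did not, and black bars are list medians; the zein members lie between -7.40 and -5.16, and the largest rise, dehydrin1, is at 7.25.

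Other genes with large rises and the same sign in all 8 lines were pathogenesis related protein4 (log2 5.70), serine acetyltransferase1, an enzyme of cysteine synthesis (log2 5.62), and pathogenesis related protein5 (log2 5.49). Further ones were HSF-transcription factor 18, of the heat shock factor family (10.4 ± 7.28 to 517.9 ± 327.5 TPM, log2 5.45), and lipid transfer protein1 (log2 5.30). The falls were led by zein genes, namely 22kD alpha zein3 (log2 -6.69), AZS22-8 (log2 -6.25), 22kD alpha zein4 (log2 -6.24), delta zein structural18 (log2 -6.16) and zein protein, 15kDa15 (log2 -6.07). The exception of lower abundance was floury3 (Zm00001d009292, chromosome 8, 52707946 to 52709109), a regulator of endosperm transcription, which went from 158.2 ± 62.7 TPM to 0.0803 ± 0.0867 TPM (log2 -7.02, SE 0.22). Among genes without a name, Zm00001d031228 (log2 8.46) and Zm00001d048348 (log2 7.65) had the largest rises and Zm00001d045937 (log2 -8.56) and Zm00001d019156 (log2 -6.55) the largest falls.

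In total, limma called 3439 genes higher and 2475 lower at 56 than at 21 DAP, 5914 of 28780, and 4346 of the 5914 had the same sign in all 8 lines. The total was 9663 at a pseudocount of 0.1 and 2961 at a pseudocount of 5. Counts of called members adjusted over the list alone were equal to those over all genes for each of the 25 lists. Camera called 11 of 23 lists, 3 up and 8 down, and 0 with an estimated correlation, where 5 lists had an unadjusted p below 0.05. When TPM was recomputed without the zein list, the median log2 change of all genes moved from 0.08 to -0.17 and the calls from 58.2% rises (3439 up, 2475 down) to 34.7% rises (2290 up, 4306 down). The balance of rises and falls is relative to that shift.

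The second comparison followed the change from stage to stage, averaged over lines. Zeins kept 32.4% ± 3.36 of the TPM sum at 28 DAP and 28.5% ± 5.16 at 35 DAP, and had 22.9% ± 8.17 at 42 DAP and 17.1% ± 13.7 at 49 DAP (SD over lines, n = 8 lines). The number of zein genes called lower was 0 of 13 at 28 against 21 DAP, 1 in each of the next 2 steps, and 13 of 13 at 49 against 42 DAP and at 56 against 49 DAP. The list medians were -2.16 and -2.87 for those last steps. Starch synthesis genes behaved alike, with 0 calls up to 42 DAP, 6 of 26 called lower at 49 against 42 DAP and 10 of 26 at 56 against 49 DAP. The share of LEA proteins and dehydrins grew at each stage, from 0.193% at 21 DAP over 0.295%, 0.504%, 1.04% and 1.68% to 3.08% at 56 DAP. Transfer layer genes were called lower at every step, 2 of 11 at 28 against 21 DAP and 6 of 11 at 56 against 49 DAP. With the line as the unit, limma called 0 zein genes at each of the 5 steps, 2 starch synthesis genes at 56 against 49 DAP and 1 transfer layer gene at 28 against 21 DAP, and 0 members of these 2 lists at the other steps.

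Genes named for single steps are those with the largest changes among called genes with the same sign in all 8 lines. At the early steps these were chitinase A1, which rose from 96.2 ± 77.8 TPM at 21 DAP to 600.4 ± 449.3 at 28 DAP (log2 3.05, SE 0.31, adjusted p = 1.29e-13) and to 3333 ± 4158 at 35 DAP (log2 2.15). The others at 28 DAP were dehydrin1, with 473.6 ± 179 TPM (log2 2.33), and Zea root protein2 (log2 2.56). The falls at 28 against 21 DAP were floury3 (log2 -3.52, to 16.3 ± 8.72 TPM) and pyruvate decarboxylase1 (log2 -1.07). At 35 against 28 DAP, stress-induced protein1 (log2 1.58) and 1-aminocyclopropane-1-carboxylate oxidase15, an enzyme of ethylene synthesis (log2 1.45), rose, and knotted1 induced1 (log2 -1.37), basal endosperm transfer layer10 (log2 -1.17) and beta glucosidase aggregating factor1 (log2 -1.13) fell. Without the 13 libraries that did not match their label, this step was averaged over 6 lines, without Q4 and Q5, and the calls of the oxidase (log2 1.42, adjusted p = 0.0721) and of beta glucosidase aggregating factor1 (log2 -0.49, adjusted p = 0.449) were lost. Whether the libraries or the 2 lines made the difference was not tested. At 42 against 35 DAP, galactinol synthase3 (26.8 ± 19.1 to 121.7 ± 94.3 TPM, log2 1.73), HSF-transcription factor 18 (log2 1.48) and HSF-transcription factor 28 (log2 1.42) rose, and floury3 (log2 -1.44), beta expansin3 (log2 -1.32) and beta glucosidase aggregating factor1 (log2 -1.17) fell.

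At 49 against 42 DAP, CNR2 (log2 1.39) and lipid transfer protein1 (log2 1.24) rose, and 22kD alpha zein5 (log2 -3.21), pathogenesis-related protein2 (log2 -1.65) and scarecrow-like1 (log2 -1.37) fell. At 56 against 49 DAP, dwarf & irregular leaf1 (10.2 ± 14.4 to 51.6 ± 58.0 TPM, log2 1.91), myb transcription factor38 (log2 1.60) and dehydrin1 (log2 1.49) rose, and brown midrib3 (log2 -2.13), glyceraldehyde-3-phosphate dehydrogenase3 (log2 -2.03) and Zea nodulation homolog1 (log2 -1.79) fell. With the line as the unit, pyruvate decarboxylase1 at 28 against 21 DAP and all genes named for the next 3 steps were no longer called. In the test over all 6 stages, 6797 of 28780 genes (23.6%) had a stage effect, and 3492 of them (51.4%) had their highest mean at 56 DAP and 1986 (29.2%) at 21 DAP, while 182 to 447 peaked at each stage between.

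The calls were 161 up and 40 down at 28 against 21 DAP, 103 and 36 at 35 against 28, 107 and 39 at 42 against 35, 157 and 148 at 49 against 42, and 238 and 491 at 56 against 49 DAP. Leaving out 1 replicate number moved the totals from 139 to between 88 (without replicate 1) and 219 (without replicate 2) at 35 against 28, from 146 to between 68 (without replicate 3) and 268 (without replicate 1) at 42 against 35, and from 729 to between 480 (without replicate 3) and 1284 (without replicate 1) at 56 against 49. Leaving out 1 line gave 67 without Q3 at 42 against 35, and 1120 without Q1 and 446 without Q8 at 56 against 49. At 49 against 42 it gave 309 up and 212 down without Q3, 105 up and 34 down without Q4, and 100 up and 90 down without Q7. Among the 4 other scalings, the percentage of rises among the calls ranged from 62.5 to 69.2 at 35 against 28 DAP (74.1 as reported), 51.9 to 66.7 at 42 against 35 (73.3), 37.5 to 44.7 at 49 against 42 (51.5) and 16.9 to 32.7 at 56 against 49 (32.6). Without the 13 libraries that did not match their label, the calls at 42 against 35 DAP were 59 up and 53 down (52.7% rises). These counts rest on the spread between libraries within lines: with the line as the unit, limma called 117, 1, 0, 0 and 314 genes for these 5 steps in turn. At this unit 2647 and 3345 genes had an unadjusted p below 0.05 at the 2 steps without a call.

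The third comparison asked how 21 and 56 DAP differed within each line. In Q4, Q7 and Q8 the zein share went from 32.4% ± 3.28, 36.1% ± 4.17 and 30.3% ± 4.13 at 21 DAP to 0.0167% ± 0.0161, 0.0161% ± 0.0167 and 0.142% ± 0.0723 at 56 DAP (SD, n = 3). In Q6 it was 28.2% ± 2.12 and 30.6% ± 3.16 and in Q1 36.2% ± 3.49 and 18.4% ± 5.06. In Q4 and Q7 the zeins were already at 0.0158% ± 0.0099 and 1.48% ± 1.28 at 49 DAP, while in Q5 they held 28.3% ± 1.76 at 49 DAP and 2.92% ± 4.23 at 56 DAP. All 13 zein genes were called lower at 56 DAP in Q2, Q4, Q5, Q7 and Q8, against 3 in Q3 and 1 in each of Q1 and Q6. The list medians were -1.84 in Q1, -5.79 in Q2, -2.52 in Q3, -11.12 in Q4, -7.15 in Q5, -0.51 in Q6, -11.99 in Q7 and -9.24 in Q8. Replicates at 56 DAP were far apart in Q2, where the zeins took 0.0662% to 18.9% of the TPM sum, and in Q5, where they took 0.0253% to 7.77%.

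Starch synthesis followed the same division: 17 of 26 genes were called lower in Q4, 15 in Q2 and Q5, 14 in Q7 and Q8, 4 in Q1, 3 in Q3 and 2 in Q6. Called higher were 6 in Q7, 5 in Q5, 4 in Q2 and Q4, 3 in Q8, 2 in Q1, 1 in Q3 and 0 in Q6. Waxy1 went from 1039 ± 130 to 0.826 ± 0.435 TPM in Q4 (SD, n = 3; log2 -9.18, adjusted p = 1.10e-16). Its values in Q6 were 1392 ± 163 and 2489 ± 502 TPM (log2 0.83, adjusted p = 0.507). Opaque endosperm2 was listed at 0 TPM in each library of Q7 at 56 DAP, after 68.95 ± 6.90 at 21 DAP, and its values in Q6 were 73.6 ± 10.35 and 118.3 ± 24.2 TPM. Dehydrin1 rose in all 8 lines, from 37.0 ± 19.8 to 3243 ± 888 TPM in Q6 (log2 6.52) and from 333.5 ± 174 to 37860 ± 1963 TPM in Q4 (log2 6.98), and its largest fold was in Q7 (log2 9.97). The LEA and dehydrin share at 56 DAP was lowest in Q6 at 0.910% ± 0.242 and highest in Q4 at 5.58% ± 0.198. Globulin1 was called higher in all 8 lines, with 5.92 in Q5 and 2.42 in Q4 on the log2 scale. Viviparous1 was called higher in 6 lines, and its log2 values in Q6 and Q3 were -0.06 (adjusted p = 0.964) and 0.76 (adjusted p = 0.155). Transfer layer genes fell in every line, 9 to 11 of the 11 members, and histone genes had 8 to 27 of 32 members called lower and 0 called higher except in Q7, with 3.

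**Figure D4:**
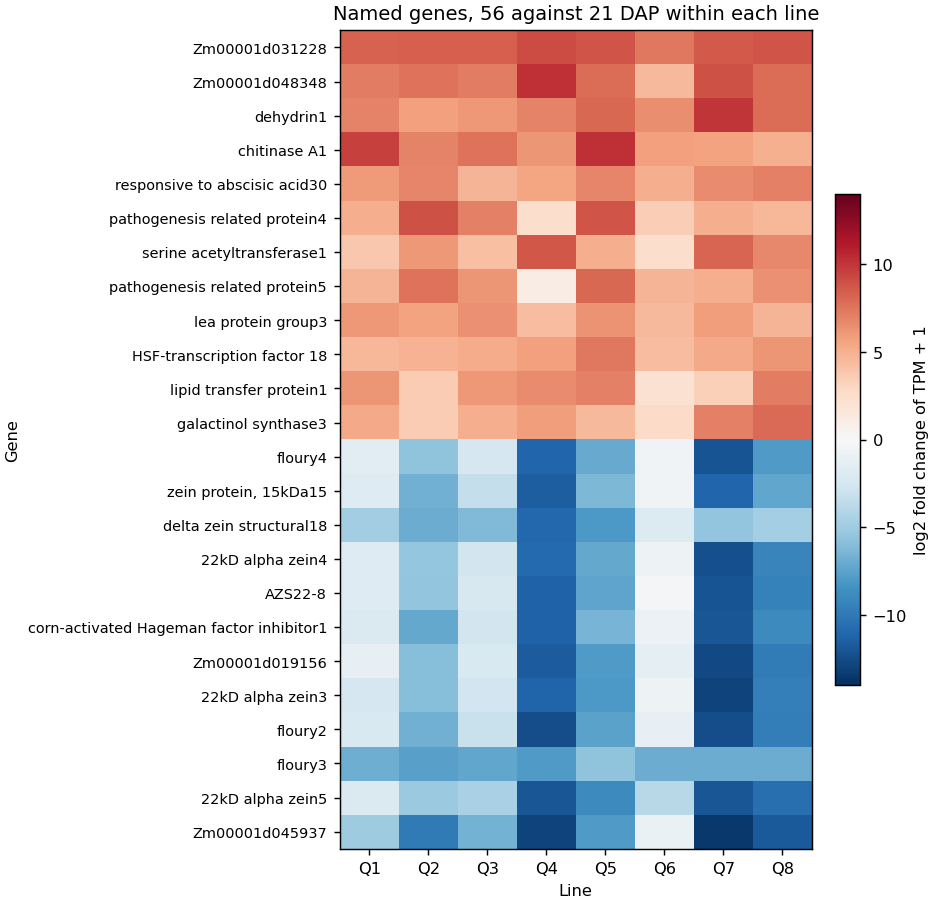
Log2 fold change of TPM + 1 between 21 and 56 DAP (colour) in each of the 8 lines (horizontal axis) for the genes with the largest rises and falls averaged over lines, the first and last including genes known only by an identifier (vertical axis). Rises such as dehydrin1 (5.73 to 9.97) were seen in each line, and falls of zein genes such as floury2 ranged from -1.19 in Q6 to -12.44 in Q4.

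Between 3632 and 11963 genes were called within single lines: 2516 up and 1116 down in Q1, 4344 and 3163 in Q2, 2719 and 1328 in Q3, 4957 and 5995 in Q4, 4410 and 2721 in Q5, 1025 and 3418 in Q6, 9175 and 2788 in Q7, and 5634 and 3343 in Q8. Called up in all 8 lines were 468 genes and called down in all 8 were 296, while 1132 genes were up in one line and down in another. The percentage of rises depended on scaling in each line. As reported and as the range over the 4 other scalings, it was 69.3 and 42.6 to 64.9 in Q1, 57.9 and 33.2 to 49.5 in Q2, 67.2 and 38.6 to 58.3 in Q3, and 45.3 and 27.7 to 51.5 in Q4. It was 61.8 and 36.5 to 53.9 in Q5, 23.1 and 25.7 to 53.7 in Q6, 76.7 and 46.5 to 64.6 in Q7, and 62.8 and 39.8 to 51.8 in Q8. In Q2, the fit on its 6 libraries alone called 3453 genes. In Q3, 2581 genes were called without replicate 3. At a pseudocount of 5 the counts were lower in every line, from 1701 in Q6 to 6888 in Q7.

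The fourth comparison asked which genes differed between lines over all stages. The largest ranges of line means were in storage protein genes. The gene 22kD alpha zein5 averaged 12100 ± 8405 TPM in Q1 and 12.6 ± 17.6 TPM in Q3 (SD, n = 18 libraries). Delta zein structural18 averaged 4590 ± 3598 TPM in Q6, 14.7 ± 19.6 in Q7 and 15.5 ± 19.5 in Q8. Zein protein3 averaged 10030 ± 4388 TPM in Q6 and 1478 ± 4078 in Q4. The values of all lines rest on the genes of the B73 reference alone, so differences between lines in single zein copies are uncertain. For other genes too, values near 0 in a line cannot be told apart from a gene that is absent there or differs from the reference. This limit holds for every comparison between lines. Outside the zeins, abscisic acid-responsive28 averaged 319.9 ± 331 TPM in Q7 and 42.7 TPM in Q6, 1.98 TPM in Q2, and at most 0.137 TPM in Q1, Q3, Q4, Q5 and Q8. HMG-transcription factor 3 averaged 128.8 ± 21.3 TPM in Q6 and 3.45 ± 6.47 TPM in Q5, and cinnamyl alcohol dehydrogenase1, of lignin synthesis, 45.3 ± 15.03 TPM in Q3 and 0.0949 ± 0.146 TPM in Q7. Further genes with wide ranges were pathogenesis related protein4 (436.5 ± 553 TPM in Q4, 5.99 ± 14.9 in Q6), and floury4 (5891 ± 3679 in Q3, 314.1 ± 216 in Q8). Others were histone 2B5 (74.8 ± 54.6 in Q5, 0.768 ± 0.376 in Q7) and precursor elicitor peptide1 (44.4 ± 16.3 in Q8, 0.834 ± 1.96 in Q3).

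Set against the mean of the other lines, the named genes with the largest differences were as follows. Higher were 22kD alpha zein5 in Q1 (log2 4.76) and Q2 (log2 4.38), cinnamyl alcohol dehydrogenase1 in Q3 (log2 2.85), cytokinin oxidase 5 in Q4 (log2 2.68), NAC-transcription factor 87 in Q5 (log2 2.28), delta zein structural18 in Q6 (log2 4.39), abscisic acid-responsive28 in Q7 (log2 5.87) and TPS6 in Q8 (log2 2.61). Lower were zein protein3 in Q1 (log2 -3.32) and Q4 (log2 -4.22), abscisic acid stress ripening9 in Q2 (log2 -3.42), 22kD alpha zein5 in Q3 (log2 -6.82), HMG-transcription factor 3 in Q5 (log2 -4.01), pathogenesis related protein4 in Q6 (log2 -4.35), and delta zein structural18 in Q7 (log2 -5.86) and Q8 (log2 -5.65). A line effect was called for 10539 of 28780 genes (36.6%). The single lines differed from the others in 923 genes for Q1, 1252 for Q2, 1358 for Q3, 1390 for Q4, 906 for Q5, 2150 for Q6, 2226 for Q7 and 1687 for Q8. These counts depended on the pseudocount: at 0.1 they ranged from 3119 in Q5 to 5738 in Q7, and at 5 the highest was 696, in Q7. In Q6 lower genes outnumbered higher ones, 1528 against 622 (28.9% higher), and they did so by less under the 4 other scalings (36.5% to 49.1% higher). Without the 13 libraries that did not match their label, and over the 6 lines that then kept all stages, the count for Q1 was 1537. Lines Q4 and Q5 then lacked a stage and were not recomputed. Their counts, like all others given with all libraries, therefore include libraries that did not match their label. So do the values of single genes over all stages in Q1, Q2, Q4, Q5 and Q6, and the mean of the other lines in each comparison.

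The fifth comparison asked whether the change with stage differed between lines. It did for 22648 of 28780 genes (78.7%). The named genes with the largest interaction F included the starch genes above, namely waxy1 (F = 9.98, adjusted p = 4.78e-18), whose change from 21 to 56 DAP ranged from 0.83 in Q6 to -9.18 in Q4, shrunken2 (-0.62 in Q6, -8.83 in Q4) and brittle endosperm2 (-0.18 in Q6, -8.06 in Q4). NAC-transcription factor 130 ranged from 0.14 in Q6 to -9.05 in Q4 and dwarf & irregular leaf1 from 0.27 in Q6 to 5.94 in Q7. Protein phosphatase homolog8, a name used for phosphatases of abscisic acid signalling, went from 40.2 ± 0.649 to 213.7 ± 23.6 TPM in Q6 (SD, n = 3; log2 2.38) and from 66.6 ± 11.8 to 3.06 ± 0.902 TPM in Q4 (log2 -4.07). Glucose translocator1 (F = 11.01), BZR-transcription factor 2 (F = 12.2) and LBD-transcription factor 44 (F = 18.5) also ranked among the 10 largest. Leaving out the 13 libraries that did not match their label also left out lines Q4 and Q5, which then lacked a stage. Over the other 6 lines the ranges of the 56 against 21 DAP change of these 3 genes were 0.39, 0.88 and 0.91, below the 1 needed for a call, with adjusted p values of 5.2e-05, 8.15e-10 and 0.0001. None of the 13 libraries was at 21 or 56 DAP, so the narrower ranges come from the lines left out. The interaction F uses all stages, and with all libraries the adjusted p values of these 3 genes were 1.88e-19, 4.78e-21 and 1.05e-27. Whether the 13 libraries or the lines left out made that difference in p was not tested. Cytidine deaminase2 ranged from 0.54 in Q7 to -2.88 in Q4. Over the 6 lines other than Q4 and Q5 its range was 1.59 instead of 3.42 and that of protein phosphatase homolog8 was 4.18 instead of 6.44. Over those 6 lines, without the mismatching libraries, 19059 genes had an interaction. Over all 8 lines the count was 12762 without replicate 3, against 22648 with all replicates.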

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

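Results are listed here where their change from 21 to 56 DAP differed between lines. The tests of mixtures, of the zein share and of the endosperm and embryo shares, and the counts without the mismatching libraries, were chosen after the results they concern were seen.

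The first pattern is the line by stage interaction, which 22648 of 28780 genes showed. Regrouping the lines within each stage gave at most 1035 genes in the other 99 of 100 splits. Such splits put the differences between lines into the spread within groups, which lowers their counts, so they cannot decide on chance for the interaction. Recomputing TPM without the zein list left 21630 genes, and leaving out the 13 libraries that did not match their label, and with them lines Q4 and Q5, left 19059, which argues against the zein share and against those libraries as the whole cause. Lines that run along 1 shared course at different speeds are a candidate explanation. The test used a maturation score, the first principal component of the changes with stage within lines, in 12670 genes past the adjusted p for the stage effect. In place of the stage, the score removed a median of 19.7% of the line-by-stage variance in 11334 genes not used for the score, against at most 18.7% in 99 reassignments of the scores. This was above every reassignment but below the share set in advance for support, so shared and separate courses cannot be told apart here, and differences in drying or harvest between lines were not tested.

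The second pattern is the set of 13 libraries that did not match the line in their label. For the libraries labelled Q4 (replicates 2 and 3) and Q5 at 28 DAP, the correlation over 10380 other genes was higher with the other of these lines than with the labelled one by at least 0.318, so an exchange of Q4 and Q5 labels or material is a candidate explanation, and no biological explanation was tested. A mixture of the labelled line with another of the 8 lines is argued against for the other 8 libraries, whose highest match to such a union was 83.77%. The libraries labelled Q4 at 35 DAP, replicates 2 and 3, had at least 97.46% of the on genes of Q4 on, together with genes that are off in Q4, and may hold material from outside the 8 lines. The last 6 libraries had at most 61.98% of their labelled line's on genes on, which argues against a mixture that includes that line, and their origin stays open.

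The third pattern is the fall of zein transcripts from 21 to 56 DAP, large in Q4, Q7 and Q8 and small in Q6. The medians of the transfer layer genes did not follow this division, at -4.68 in Q4, -3.67 in Q7, -3.08 in Q8 and -3.90 in Q6. Embryo surrounding region genes had their lowest median in Q6 (-1.22, 7 of 11 called lower). These 2 lists took 0.148% and 0.00849% of the TPM sum at 21 DAP, against 32.6% for zeins. A fall of log2(TPM + 1) cannot exceed the level at 21 DAP, so the floor may limit these medians. At 56 DAP the transfer layer share still ranged from 0.0004% to 0.0221% over lines. The medians therefore do not decide whether the 2 lists followed the division. A smaller share of endosperm in the RNA, or embryo transcripts taking a larger part of the TPM sum, would as the whole cause lower the zein genes by 1 common amount. In Q8 the log2 changes of the 10 zein genes with at least 10 TPM at 56 DAP lay 2.83 apart (-6.81 to -9.64, at least 2.70 apart in each library), which argues against both as the whole cause there, while a common part of the fall stays open. In Q4 and Q7 the mean changes of the 4 and 3 such genes lay 0.54 and 0.16 apart (0.23 to 1.12 and 0.30 to 0.95 in single libraries), so with so few genes above the floor both explanations cannot be told apart from a loss of the transcripts themselves. Members of 2 other endosperm lists went both ways and decide nothing, since their genes are not known to be limited to the endosperm: against zein medians of -11.12 in Q4 and -11.99 in Q7, the starch list had -2.73 (4 up, 17 down) and -2.30 (6 up, 14 down), and the endosperm transcription factors -1.02 (1 up, 5 down) and -0.30 (1 up, 3 down). Embryo transcripts as the whole cause would also lower genes outside the embryo, and the medians of all genes (-0.06 in Q4, 0.41 in Q7) and of the pericarp list (-1.90 and -0.71) count against it only as far as the embryo does not express those genes, which no table here shows, while differences between lines in the age at which transcripts are lost stay open, and reads shared between zein copies, and copies that differ from the B73 reference, were not tested.

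Of the named genes, 6 had opposite changes past the adjusted p in different lines. Abscisic acid stress ripening5 differed most, by 8.13 on the log2 scale between Q1 (3.07) and Q4 (-5.06), with an interaction adjusted p of 2.50e-08. Protein phosphatase homolog8 differed by 6.44 between Q6 (2.38) and Q4 (-4.07), with a range of 4.18 over the 6 lines other than Q4 and Q5 without the mismatching libraries, Zea root protein2 by 5.82 between Q2 (3.001) and Q4 (-2.82; interaction adjusted p = 0.0202), and NAC-transcription factor 87 by 5.65 between Q6 (2.03) and Q4 (-3.62). Histone1a differed by 3.15 between Q7 (1.16) and Q4 (-1.98), and WRI1 transcription factor1 by 2.95 between Q7 (1.09) and Q4 (-1.86). The summed shares of 2 lists had all libraries at 56 DAP above those at 21 DAP in some lines and below them in Q6, a difference that was not tested. The share of embryo and abscisic acid maturation regulators went from 0.0087% to 0.0381% in Q7 and from 0.0106% to 0.0088% in Q6, changes that differ by 0.0312 points. The share of cytosolic ribosomal proteins went from 0.426% to 0.557% in Q3 and from 0.585% to 0.406% in Q6, changes that differ by 0.309 points. With the zein list left out of the sum, the ribosomal share went from 0.622% to 0.607% in Q3 and was lower at 56 DAP in 8 of 8 lines, so its opposite directions were lost, while that of the regulators still rose in Q7 (0.0135% to 0.0381%) and fell in Q6 (0.0148% to 0.0127%).

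Other splits of the samples test only whether the stage or line labels matter at all. For the stage effect and the line effect as a whole, only the real split gave as many genes. Each split mixes the stages of a line, or the lines of a stage, so real differences enter the spread within its groups. Low counts in the other splits were therefore likely beforehand. They cannot show how many of the called genes are due to chance, and cannot decide on chance for a single step or a single line. With the line as the unit, limma called 1, 0 and 0 genes at 35 against 28, 42 against 35 and 49 against 42 DAP. At 56 against 21 DAP it called 3431 up and 2465 down. With stages regrouped within lines, 1 of 100 splits, the real one, gave as many genes at 56 against 21 DAP (5914, highest other 0), 35 against 28 (139, highest other 1), 42 against 35 (146, 7), 49 against 42 (305, 1), 56 against 49 (729, 584) and for the stage effect (6797, 3). At 28 against 21 DAP, 2 of 100 splits did (201, highest other 712), and a split with several times the real count points to a structure of the samples. For the gene lists, 9 of 100 splits gave at least the 11 lists called (highest other 14), so chance is not excluded. With lines regrouped within stages, only the real split gave as many genes for each line against the others (Q1 923, highest other 4; Q2 1252, 3; Q3 1358, 22; Q4 1390, 8; Q5 906, 270; Q6 2150, 9; Q7 2226, 34; Q8 1687, 67) and for the line effect (10539, 4). Within lines, 10 splits are too few for a share under 0.05, and the real and highest other counts were 3632 and 11 in Q1, 7507 and 4779 in Q2, 4047 and 458 in Q3, 10952 and 48 in Q4, 7131 and 2465 in Q5, 4443 and 39 in Q6, 11963 and 3352 in Q7, and 8977 and 550 in Q8.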

How the results depend on the processing

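Among the alternatives, leaving out the libraries that did not match their label was chosen after seeing the data. Of 3014 values of 112 named genes under the alternatives, 2921 kept their direction and side of the threshold, 87 were no longer past it, 6 newly passed and 0 reversed. Many of these genes were named for large called changes in the same data, so few reversals were likely beforehand. The 5914 genes at 56 against 21 DAP were called again in full with the replicate block and with robust variances. Leaving out the mismatching libraries does not test them, since none was at 21 or 56 DAP. They shared 5213 genes with the 5680 called after median-of-ratios scaling, 5106 of 5589 after quantile normalization, 4750 of 6596 without the zein list and 5063 of 5351 with FPKM.

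The pseudocount moved most counts. At 0.1 there were 9663 genes at 56 against 21 DAP, 699, 571, 502, 934 and 1864 for the 5 steps between stages in turn, 3257, 3612, 4025, 4113, 3119, 5351, 5738 and 4498 for Q1 to Q8 against the others, 11881 for the stage effect and 17099 for the line effect. At 5 there were 2961 genes at 56 against 21 DAP, 93, 47, 57, 114 and 266 for the steps, 1779, 3879, 1948, 6090, 3691, 1701, 6888 and 4938 within Q1 to Q8, 2.2e+02 (147 up, 74 down), 327, 379, 376, 2.3e+02 (146 up, 82 down), 687, 696 and 485 for Q1 to Q8 against the others, 3308 for the stage effect, 4187 for the line effect and 13762 for the interaction.

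Counts between adjacent stages depended on the samples and the unit. Without 1 replicate number in turn they ranged from 88 to 219 at 35 against 28 DAP, 68 to 268 at 42 against 35 and 480 to 1284 at 56 against 49, and the counts were 2581 to 4699 in Q3 and 12762 to 23586 for the interaction. With the line as the unit, limma called 117 genes at 28 against 21 DAP, 1 at 35 against 28, 0 at 42 against 35 (2647 at an unadjusted p below 0.05), 0 at 49 against 42 (3345 at an unadjusted p below 0.05) and 314 at 56 against 49. Counts were 1120 without line Q1 and 446 without line Q8 at 56 against 49 DAP, 67 without line Q3 at 42 against 35, and 5.2e+02 (309 up, 212 down) without line Q3, 139 without line Q4 and 190 without line Q7 at 49 against 42. The fit on the 6 libraries alone gave 3453 genes in Q2. Without the mismatching libraries, Q1 against the others had 1537 genes, over fewer lines. Except where the construction is named, the cause was not tested.

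With an estimated correlation, camera called 0 lists against 11 with the preset one, and 5 lists had an unadjusted p below 0.05. After median-of-ratios scaling, camera lost the endosperm transcription factors (adjusted p = 0.0688) and called the cell death and protein mobilisation list up (adjusted p = 0.047). After quantile normalization it lost the endosperm transcription factors (adjusted p = 0.0543) and the antioxidant list (adjusted p = 0.055), and called the cytosolic ribosomal proteins down (adjusted p = 0.00564). The share of cytosolic ribosomal proteins was 0.439% at 21 DAP and 0.483% at 56 DAP, higher in 7 of 8 lines (exact p = 0.234). Without the zein list in the sum it reversed, with a mean difference of -0.117 points and higher values in 0 of 8 lines (exact p = 0.00781, adjusted p = 0.015), and the cause was not tested. As for the replicate block, replicate numbers do not pair the samples: the mean correlation of residuals was 0.0066 for the same number and -0.0031 for other numbers, and the block left 22508 interaction genes against 22648. A count model with edgeR or DESeq2 was not run, since the tables used here hold no counts. Depth was 5.997 to 9.75 Gb of aligned bases, and what it limits among genes of low TPM was not tested.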

Other observations

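The observations in this part were chosen after seeing the data. Heat shock factors stood out among the named transcription factor families at 56 against 21 DAP: 11 of 28 tested HSF genes were called higher and 0 lower, with a median of 0.75 (Fisher test against the other named transcription factor genes, p = 0.000704, adjusted over 44 tests p = 0.031). The Fisher test treats genes as independent, and correlation between genes measured in the same libraries was not taken into account. The numbers higher were 11 after median-of-ratios scaling, 10 after quantile normalization and 9 without the zein list, with 0 lower in each. The largest changes were in HSF-transcription factor 18 (log2 5.45), HSF-transcription factor 28 (1.45 ± 0.601 to 76.8 ± 58.6 TPM, SD over 8 lines, log2 4.61), HSF-transcription factor 4 (8.28 ± 1.14 to 45.25 ± 16.2 TPM, log2 2.26), HSF-transcription factor 5 (log2 2.12) and HSF-transcription factor 11 (log2 1.99). Among 89 WRKY genes, 18 were higher and 3 lower (adjusted p = 0.565), and among 94 NAC genes 11 were higher and 5 lower (adjusted p = 0.763), the latter with a median of 0.18 that was -0.08 without the zein list.

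The maturation score described above, scaled to 0 in the lowest and 100 in the highest of the 48 groups, was at 56 DAP 43.65 ± 5.96 in Q1, 77.0 ± 29.7 in Q2, 53.2 ± 4.03 in Q3, 97.1 ± 1.89 in Q4, 74.96 ± 17.5 in Q5, 31.6 ± 5.30 in Q6, 100 ± 3.68 in Q7 and 91.6 ± 3.85 in Q8 (SD, n = 3). It did not rise with age at every step. In Q1 the mean was 51.2 ± 13.3 at 49 DAP, and in Q3 it was 46.5 ± 12.8 at 42 DAP and 32.7 ± 8.66 at 49 DAP. At 49 DAP the score was 97.1 ± 1.24 in Q4, 83.5 ± 15.2 in Q7 and 18.25 ± 3.76 in Q6. Single libraries at 56 DAP ranged from 42.7 to 95.25 in Q2 and from 55.6 to 89.7 in Q5, so the order of lines near these is not settled.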
